A study of Mus musculus with 8 samples.

How the data were processed

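Total RNA from p53-null mouse liver and liver tumours was measured on 2 kinds of Affymetrix expression array. Biotin-labelled cRNA was made from 6 microg of total RNA per array, per the labels. The deposited values are the MAS5 expression signal of each probe set on a linear scale, per the submitters' processing notes. The MAS5 version and target are not given in the sources used here, and the series design names ArrayAssist 4.0 for the submitters' own clustering of genes. On each of the arrays the mean of the signals without the lowest and highest 2% was 150, so the arrays were used as scaled by the authors.

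The 6 tumour arrays had 45101 probe sets, of which 34958 were annotated to 1 gene symbol, 932 to several and 9211 to none. The array used for the adenovirus samples had 22690 probe sets, of which 20393 had 1 symbol, 691 several and 1606 none. Probe sets with 1 symbol in the platform annotation were used, with names checked against a RefSeq gene table of the mouse genome. Each gene was represented by its probe set with the highest mean. Levels were log2 of the signal plus 32, and fold changes and log2 differences are on that scale. An array has no count of molecules behind a value, and precision was limited by the number of arrays.

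For the tumours, genes with a mean level at or above the median of all probe sets were kept, which left 11979 of 18194 genes. The groups of 3 tumours were compared with limma 3.58.1 in R 4.3.3, with a variance trend in the empirical Bayes step and two-sided tests. A gene passed at a Benjamini-Hochberg adjusted p below 0.05. Of 47 gene lists fixed before the data were examined, the 45 with at least 5 tested members were tested with camera in limma, with a preset correlation between genes of 0.01, adjusted over the lists. The same lists were also tested with an estimated correlation and with fry. The adjusted p beside a named member of a list is the one over all genes unless it is called adjusted over the list alone.

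The adenovirus samples were 1 array per group, so no test between them was made. Genes with a signal at or above the array median on at least 1 of the 2 arrays were compared, and a ratio of at least 2 was counted. The median log2 ratio of each list was ranked among 10000 random lists of the same size, drawn within 20 bins of mean level. A list outside the central 95% of those random lists stood apart on this pair of arrays, which says nothing about other mice. The fold changes of both data sets were compared across genes by Spearman and Pearson correlation, and the value was set against the 10 ways to split the 6 tumours 3 against 3.

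The rule for named genes, the tests and the alternatives were also set before the data were examined, except for the additions named below. In each direction up to 12 tumour genes were named, first those past the threshold with no overlap between the groups. The remaining places went to genes with the smallest unadjusted p among those with no overlap and a log2 difference of at least 1, and these are given as not past the threshold. From each list up to 4 members with the smallest p were eligible, as were members past the threshold adjusted over the list alone. For the adenovirus pair, the 12 highest and 12 lowest ratios and up to 4 members of each list were eligible. Predicted genes and clone names were passed over.

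The alternatives were quantile normalization, median centring, a pseudocount of 1 and a higher one, no level filter, a filter at percentile 75, all probe sets, the mean of the probe sets of a gene, no variance trend, array weights, a Y-linked covariate and each tumour left out in turn. Added after the data were seen were the neutrophil list without S100a8 and S100a9, the macrophage list without genes shared with the other immune lists, the probe sets without a single symbol, and a block for the level of the 18S control.

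The code was tested on simulated data. In simulated tumours, 56 of 100 genes changed 4-fold and 82 of 100 genes changed 8-fold were called, with 5 unchanged genes called. None was called where nothing had been changed (0 genes), and a shifted list passed with an adjusted p of 4.2e-06 in camera. The simulated genes varied independently of each other, while the estimated correlation among macrophage markers in the tumours was 0.60. The list test was thus not tried under such a correlation. In a simulated adenovirus pair, a shifted list lay at percentile 100 of the random lists, and 5 of 44 other lists lay outside the central 95%. Terc and Trp53 were not analysed here.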

Results

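Gene expression was measured in p53-null mice on a C57BL/6J background, in relation to telomere dysfunction of the liver. The tumour data set held 6 hepatocellular carcinomas of HBs transgenic mice aged 12 to 15 months, with 1 tumour per array. Of these, 3 came from mice with the telomerase RNA gene (mTERC+) and 3 from mice without it (mTERC-). The adenovirus data set held 2 arrays of liver taken 48 hours after intravenous infection. One array carried RNA pooled from 3 mice given a virus for TRF2DBDM, a truncated form of the telomere-binding protein TRF2, and the other carried RNA pooled from 3 mice given a GFP virus. The tissue field of the labels reads hepatocytes for every array, while the series design describes whole liver and tumour RNA.

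The median signal was 54.5 to 59.4 on 5 of the tumour arrays and 75.1 on mTERC- tumour 2. That array had a 3'/5' ratio of 13.8 for the Gapdh control, against 0.983 to 1.18 on the other tumour arrays. Its ratio for the Actb control was 2.28, against 1.30 to 1.64 on the others. Its mean correlation with the other arrays was 0.798, and the other tumours lay between 0.852 and 0.862. The signal of the 18S control was 319 and 349 on mTERC- tumours 2 and 3 and 11010 to 27810 on the other 4 arrays. The correlation between arrays averaged 0.850 within groups and 0.847 between groups.

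The first comparison asked which genes differed between carcinomas that arose without and with the telomerase RNA. S100a8 (Entrez Gene 20201), a calcium-binding protein abundant in neutrophils, was higher in mTERC- tumours, at a signal of 5406 ± 2391 against 415 ± 324 (SD, n = 3 each). The log2 difference was 3.75 (SE 0.50), or 13.5-fold, with an adjusted p of 0.0246 in limma and no overlap between the groups. The call of S100a8 was lost under several alternatives, among them without mTERC- tumour 2 (adjusted p = 0.344 in limma). Its partner S100a9 had a signal of 8076 ± 2574 against 830 ± 902 and did not pass over all genes (adjusted p = 0.579 in limma). The 9 tested neutrophil markers all had a higher mean in mTERC- tumours, and as a list they rose, with a median log2 difference of 1.58 and an adjusted p of 1.4e-09 in camera. The adjusted p of this list was 0.553 with an estimated correlation. Adjusted over the list alone, 5 members passed, which were S100a8, S100a9, the granule protein genes Camp and Ngp, and Csf3r, the receptor of a neutrophil growth factor. Camp had a log2 difference of 2.23, Ngp of 1.97 and Csf3r of 1.51. Their signals varied widely among the mTERC- tumours, at 424 ± 450, 703 ± 857 and 296 ± 258 (SD, n = 3), and for Camp the groups overlapped. The list score was 1.86, 0.89 and 0.11 in mTERC- tumours 1, 2 and 3. Without S100a8 and S100a9 the list median was 1.51. The list median was 1.38 without mTERC- tumour 1 (1.13 with the same probe sets as in the full fit) and 2.73 without mTERC- tumour 3. It was 1.03 with the higher pseudocount. With a block for the 18S control it was 3.73, but that block leaves mTERC- tumour 1 as the only tumour set against the mTERC+ group.

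**Figure D1:**
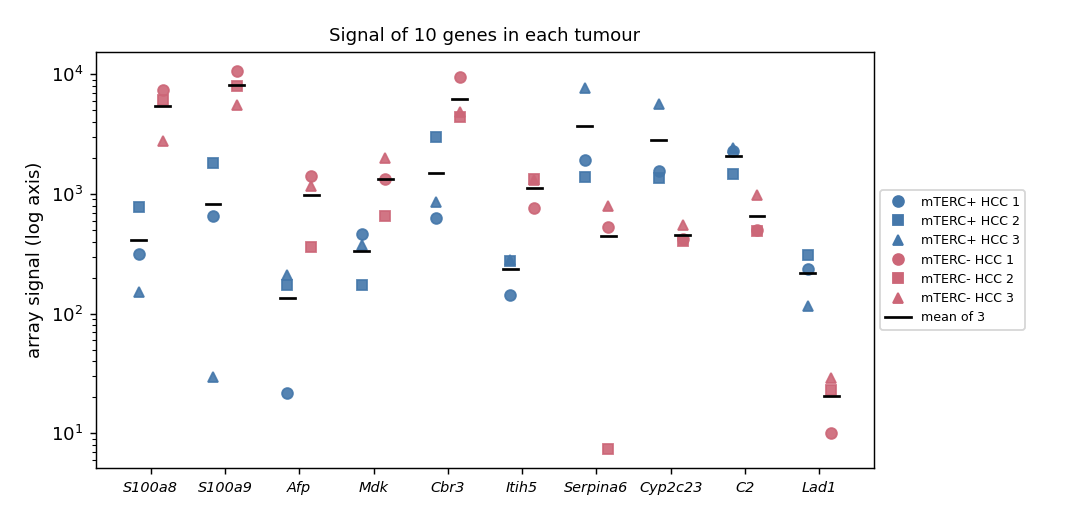
Array signal (log axis) of 10 genes in each of the 6 tumours; blue points are mTERC+ and red points mTERC-, each marker shape is 1 tumour and the black line is the mean of 3. S100a8 lay between 150.4 and 776 in the mTERC+ and between 2759 and 7407 in the mTERC- tumours, and it is the only one of these genes past the adjusted threshold.

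Several groups of immune and vascular genes fell as lists in mTERC- tumours, while other immune and stromal lists did not pass in camera. Among the latter were T and NK cell markers (median log2 difference 0.12, adjusted p = 0.848) and B and plasma cell markers (0.04 and 0.799). Chemokines and cytokines (-0.14 and 0.890), platelet markers (-0.11 and 0.397) and stellate and fibroblast markers (0.08 and 0.799) did not pass either. Of 30 tested macrophage markers, 28 had a lower mean, with a median log2 difference of -0.62 and an adjusted p of 1.8e-06 in camera (adjusted p = 0.553 with an estimated correlation). Cybb, a subunit of the phagocyte oxidase, had a signal of 1278 ± 627 against 3330 ± 1357, and Mpeg1 had 2424 ± 532 against 5315 ± 2116 (SD, n = 3 each). Adgre1, a surface receptor of macrophages, and the complement gene C1qb had log2 differences of -1.21 and -1.37. All 11 antigen presentation genes had a lower mean, with a median of -0.80 and an adjusted p of 1.1e-05 in camera (adjusted p = 0.553 with an estimated correlation). These included the class II genes H2-Aa, at -1.11, H2-Ab1, at -1.09, and Cd74, the invariant chain, at -1.08. Of 24 endothelial markers 20 had a lower mean, with a median of -0.37 and an adjusted p of 0.00574 in camera (adjusted p = 0.553 with an estimated correlation). Icam2, an endothelial adhesion molecule, had 66.6 ± 70.4 against 270.3 ± 27.5 and was the 1 member past the threshold adjusted over the list alone. Of 43 interferon response genes 32 had a lower mean, with a median of -0.26 and an adjusted p of 0.00802 in camera (adjusted p = 0.691 with an estimated correlation). Mx1, an antiviral gene of that list, had a log2 difference of 1.43. None of these members passed over all genes in limma. Without mTERC+ tumour 2 the macrophage median was -0.02 (adjusted p = 0.447 in camera) and the interferon median was 0.05 (adjusted p = 0.948 in camera), and the antigen presentation median was -0.49. Without mTERC+ tumour 3 the macrophage median was -1.29, without mTERC- tumour 2 the interferon median was -0.10 (adjusted p = 0.164 in camera), and without mTERC+ tumour 1 it was -0.51. The endothelial call was lost without mTERC- tumour 3, with a median of -0.18 (adjusted p = 0.135 in camera), and with the Y-linked covariate, with a median of -0.21 (adjusted p = 0.0847 in camera). With that covariate the interferon median was -0.47. With the 18S block none of these lists passed in camera, and the medians of the macrophage, antigen presentation, endothelial and interferon lists were -0.31, -0.26, -0.12 and -0.21.

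Genes of cell division rose as lists in mTERC- tumours. Of 34 mitosis genes 29 had a higher mean, with a median log2 difference of 0.43 and an adjusted p of 0.000655 in camera (adjusted p = 0.553 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, had a log2 difference of 1.38 (SE 0.71), and Aurka, a spindle kinase, of 1.03 (SE 0.59). Of 15 chromatin genes 10 had a higher mean, with a median of 0.45 and an adjusted p of 0.0163 in camera (adjusted p = 0.553 with an estimated correlation). Ncapg, a condensin subunit, had a signal of 136 ± 72.7 against 14.7 ± 6.41 (SD, n = 3 each). Of 38 DNA replication genes 29 had a higher mean, with a median of 0.19 and an adjusted p of 0.0305 in camera (adjusted p = 0.553 with an estimated correlation). Cdc45, a part of the replicative helicase, had a log2 difference of 0.86 and Ccne1, a G1/S cyclin, of 0.81. No member of these lists passed over all genes or adjusted over the list alone. The mitosis call was lost without mTERC- tumour 3 (median 0.30) and without mTERC+ tumour 3 (median 0.26), and its median was 0.64 without mTERC- tumour 1 and 0.28 with the higher pseudocount. The chromatin and replication calls were lost without the same tumours, at 0.41 and 0.32 for chromatin and 0.23 and 0.05 for replication. The chromatin call was also lost without mTERC- tumour 2 (median 0.30, or 0.36 and an adjusted p of 0.0310 in camera with the same probe sets as in the full fit), and the replication call without mTERC- tumour 1 (median 0.14). The chromatin call was lost with the filter at percentile 75 and the mean of probe sets (adjusted p of 0.243 and 0.142 in camera), and the replication call with no level filter, no variance trend and the Y-linked covariate (0.0888, 0.0504 and 0.163). The replication median was 0.32 without mTERC- tumour 2, 0.32 without mTERC+ tumour 1 and 0.40 without mTERC+ tumour 2. With the 18S block the medians of the mitosis, chromatin and replication lists were 0.09, 0.29 and 0.32, and none passed in camera. In mTERC+ tumour 3 the mitosis score was -0.78, the lowest of the 6.

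Genes of gluconeogenesis, hepatocyte function and cholesterol synthesis fell as lists in mTERC- tumours, while 5 other lists of liver metabolism did not pass in camera. These were conjugation and transport (median log2 difference -0.14, adjusted p = 0.168), lipogenesis (-0.14 and 0.199), cytochrome P450 (-0.19 and 0.590), bile acids (-0.08 and 0.738) and fatty acid oxidation (-0.09 and 0.827). Of 28 genes of gluconeogenesis and the urea cycle 23 had a lower mean, with a median log2 difference of -0.42 and an adjusted p of 0.000103 in camera (adjusted p = 0.553 with an estimated correlation). Hpd and Hal, enzymes of tyrosine and histidine breakdown, had log2 differences of -1.86 (SE 0.57) and -1.07 (SE 0.42). Both are also on the hepatocyte function list, so these lists are not independent of each other. Pcx, the gene of pyruvate carboxylase, had a signal of 1526 ± 796 against 2708 ± 399 (SD, n = 3 each). Of 36 hepatocyte function genes 26 had a lower mean, with a median of -0.12 and an adjusted p of 0.0398 in camera (adjusted p = 0.553 with an estimated correlation). Of 20 cholesterol synthesis genes 12 had a lower mean, with a median of -0.22 and an adjusted p of 0.0305 in camera (adjusted p = 0.553 with an estimated correlation). The mean of Srebf2, a regulator of that pathway, was 251 ± 62.8 against 441 ± 12.7. No member passed over all genes or adjusted over the list alone. The list of hepatocyte function did not pass without mTERC- tumour 2, the array with the Gapdh ratio of 13.8, where its median was -0.04. It also did not pass without mTERC- tumour 3 (median -0.18) or mTERC+ tumour 3 (median -0.08), and its median was -0.28 without mTERC- tumour 1. Its call was lost as well with quantile normalization, a pseudocount of 1, no level filter, no variance trend and array weights (adjusted p of 0.223, 0.0593, 0.0505, 0.107 and 0.113 in camera). Its median was -0.06 with quantile normalization, -0.22 with the filter at percentile 75, -0.24 with the mean of probe sets and -0.22 with the Y-linked covariate. The gluconeogenesis list passed with each tumour left out in turn, with a median of -0.21 without mTERC- tumour 2 and -0.24 without mTERC+ tumour 1, and with the Y-linked covariate it was -0.26. The cholesterol list was lost without mTERC- tumours 1 or 3 (medians -0.24 and -0.27) and without mTERC+ tumours 2 or 3 (-0.16 and -0.32). It was lost as well with quantile normalization, the filter at percentile 75 and no variance trend (adjusted p of 0.125, 0.0752 and 0.0675 in camera). With the 18S block the medians of the gluconeogenesis, hepatocyte function and cholesterol lists were -0.05, 0.01 and -0.19, and none passed in camera.

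**Figure D2:**
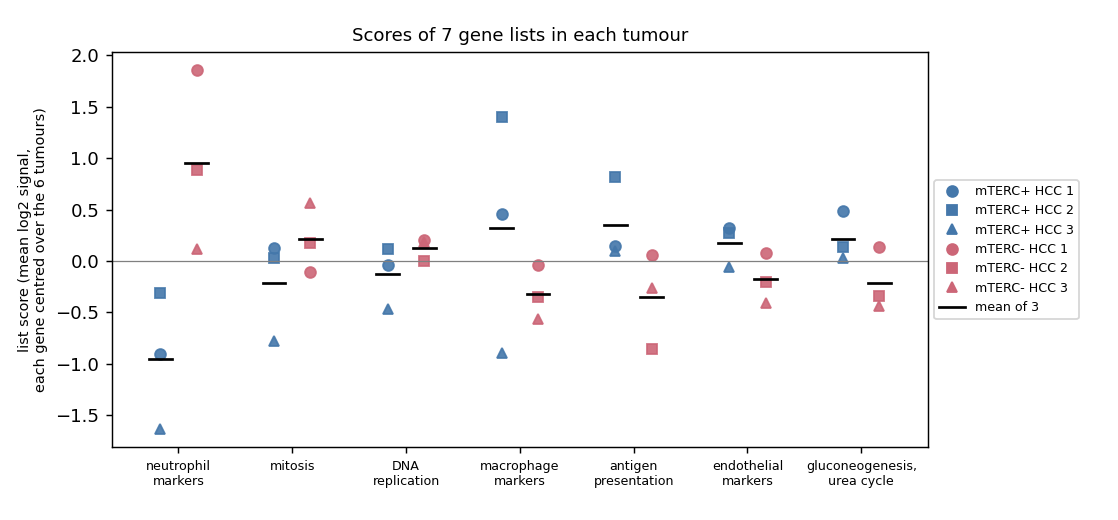
Score of 7 gene lists in each of the 6 tumours, as the mean log2 signal of the tested members after centring each gene over the tumours; blue points are mTERC+ and red points mTERC-, each marker shape is 1 tumour and the black line is the mean of 3. The macrophage score spans -0.90 to 1.40 within the mTERC+ group, which exceeds the distance between the group means.

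Other single genes did not pass the threshold over all genes, and the values of those with the smallest p follow. Afp, the gene of alpha-fetoprotein, had a signal of 975.4 ± 549 in mTERC- and 135 ± 99.95 in mTERC+ tumours (SD, n = 3 each), a log2 difference of 2.66 (SE 0.58, adjusted p = 0.735 in limma). The fetal gene list as a whole did not pass (adjusted p = 0.195 in camera), but Afp, Igfbp1 and Meg3 did adjusted over the list alone. The growth factor gene Mdk had 1332 ± 671 against 337 ± 146, and Itih5 had 1133 ± 323 against 234 ± 77.8. Cbr3 and Srxn1, both genes of the oxidative stress response, had log2 differences of 2.29 and 1.56 and passed adjusted over their list alone. The list itself did not pass (adjusted p = 0.0661 in camera). Of its 23 tested members 15 had a higher and 8 a lower mean, with a median log2 difference of 0.10. Wnt4 had a mean of 406 ± 500.3 against 13.4 ± 9.23. In the other direction, Serpina6, the carrier of glucocorticoids in blood, had 442 ± 399 against 3682 ± 3524. Cyp2c23 had 457 ± 78.4 against 2833 ± 2394, and Lad1 had 20.6 ± 9.61 against 220 ± 96.4. The complement genes C2 and C1s1 had log2 differences of -1.64 (SE 0.37) and -1.57 (SE 0.37). Apart from S100a8, the smallest adjusted p of any gene tested through a probe set with 1 symbol was 0.313 in limma, for Itih5.

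The telomere maintenance list had a median log2 difference of 0.09 over 22 genes (adjusted p = 0.590 in camera). Tert had a signal of 66.9 ± 23.5 against 44.3 ± 19.6, near the median of the arrays, and Terf2 had 114 ± 37.1 against 114 ± 39.0 (SD, n = 3 each). The list of p53 targets, in tumours that lack p53, had a median of 0.06 over 27 genes and a mean of -0.02 (adjusted p = 0.832 in camera). The lists of DNA damage repair, cell cycle inhibitors, pro-apoptotic and anti-apoptotic genes did not pass either, with adjusted p values in camera of 0.424, 0.827, 0.449 and 0.890.

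Over all genes with a probe set of 1 symbol, limma found 1 gene higher and 0 lower in mTERC- tumours. Of these genes, 604 had an unadjusted p under 0.05, where chance gives about 599. The groups did not overlap for 1215 genes, or 10.1%, where chance gives 10%. The call of S100a8 was lost without mTERC- tumour 2 (log2 difference 3.61, SE 0.57, adjusted p = 0.344 in limma), without mTERC+ tumour 1 (3.71, SE 0.58, 0.112) or 3 (3.24, SE 0.49, 0.117), and under several settings. Over the alternatives set before the results were seen that give 1 value per gene, its log2 difference lay between 3.24 and 4.31 and its adjusted p between 0.0064 and 0.344. Of the 45 lists 11 passed in camera, 0 with an estimated correlation and 0 in fry, and with the 18S block 2 did, the neutrophil markers and the ribosomal proteins.

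The second comparison asked what changed in p53-null liver 48 hours after TRF2DBDM was delivered, against GFP. There were no replicates, so the values below carry no error and describe these 2 pools. Several lists of differentiated liver metabolism were higher in the TRF2DBDM pool. The list of gluconeogenesis and the urea cycle had a median log2 ratio of 1.47 over 27 genes, of which 17 were at least 2-fold higher and 0 at least 2-fold lower. Bhmt, which remethylates homocysteine, had a signal of 6346 against 661, and Hpd had 7184 against 1293. The cytochrome P450 list had a median of 1.44 over 28 genes, with Cyp2f2 at 3585 against 243, Cyp1a2 at 1486 against 132 and Cyp2c29 at 1728 against 187. The conjugation and transport list had a median of 1.07 over 26 genes, with Ugt2b5, a glucuronyl transferase, at 1273 against 132. The bile acid list had a median of 0.83, with Cyp8b1, the sterol 12-hydroxylase, at 337 against 10.2. The hepatocyte function list had a median of 0.77 over 34 genes, of which 31 were higher, and it shares members with the gluconeogenesis list, among them Hpd. Each of these medians lay at percentile 100 of the random lists. The cholesterol synthesis list did not stand apart, with a median of -0.005 at percentile 54.1.

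Macrophage markers had a median log2 ratio of 0.88 over 26 genes, of which 21 were higher, with Lyz2, a lysozyme, at 550 against 134 and Csf1r, a growth factor receptor of macrophages, at 662 against 181. Cd14 of the same list was lower, at 353 against 1261. The antigen presentation list had a median of 0.53, and all 10 members were higher. Lists of female-biased and male-biased liver genes had medians of 0.91 and 0.46, oxidative phosphorylation of 0.51, lipogenesis of 0.49, circadian genes of 0.46 and fatty acid oxidation of 0.25, all above the central 95% of random lists.

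The interferon response list was lower in the TRF2DBDM pool, with a median log2 ratio of -0.71 over 37 genes, of which 32 were lower and 12 at least 2-fold so. Dhx58, a cytosolic RNA sensor, had a signal of 60.4 against 427, Isg20 had 54.2 against 319 and Oasl2 had 119 against 542. The neutrophil list had a median of -0.66 over 9 genes, of which 6 were lower, with S100a9 at 556 against 1002. The cholangiocyte and progenitor list had a median of -0.63 over 14 genes, with Anxa5 at 657 against 2710 and Cd24a at 55.7 against 298. The mitosis list had a median of -0.42, and 32 of 38 genes were lower, among them Plk1, a mitotic kinase, at 531 against 1292, and Foxm1, a regulator of mitotic genes, at 65.5 against 197. The glycolysis list had a median of -0.22 at percentile 2.49 of the random lists, with Pkm at 462 against 1501.

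**Figure D3:**
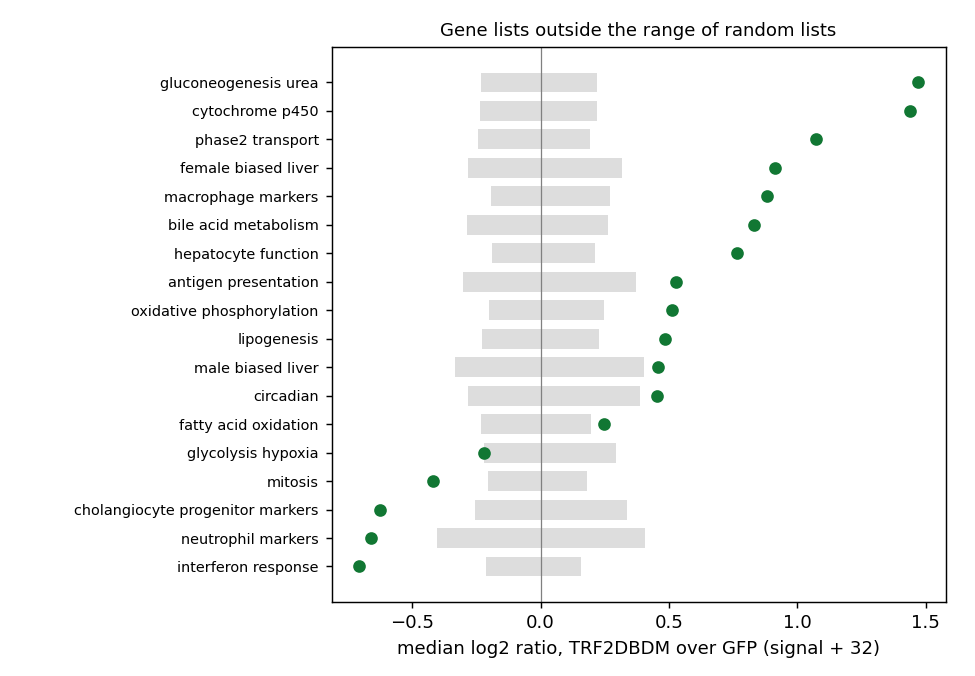
Median log2 ratio of signal (plus 32), TRF2DBDM over GFP, for the 18 gene lists outside the range of random lists; green points are the lists and grey bars the central 95% of 10000 random lists of the same size and level. The highest median is 1.47, for gluconeogenesis and the urea cycle, and the lowest is -0.71, for the interferon response.

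Single genes were ranked by the log2 ratio with the pseudocount added to each signal, and the signals alone give another order. On that scale the highest was Inmt, an indole methyltransferase (log2 ratio 4.07, signals 2016 against 89.8). Car3, a carbonic anhydrase, followed (4.05, 3588 against 186), and then Hsd17b6 (3.74, 929 against 40.1). The lowest log2 ratio on that scale was that of Sprr1a, an epithelial envelope protein (-4.04, 483 against 8426). Cyp26a1, which degrades retinoic acid, followed (-3.75, 65.9 against 1282), and then Fads3 (-3.60, 7.4 against 444). The signal of Fads3 in the TRF2DBDM pool was below the pseudocount, so its ratio depends on that setting. Slpi had 285 against 1836 and Anxa2 had 933 against 4711. The p53 target list had a median log2 ratio of 0.22, at percentile 91.0, and the telomere maintenance list had 0.09, at percentile 64.0, so neither stood apart. Terf2 had a signal of 146 against 105, and whether its probe set detects the delivered TRF2DBDM transcript is not known.

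Of 7788 genes compared, 360 were at least 2-fold higher in the TRF2DBDM pool and 226 at least 2-fold lower. Higher genes were 61.4% of these, but 45.7% after median centring (280 higher and 333 lower), which shifts the median of all genes by -0.114. Of 45 lists measured, 13 lay above and 5 below the central 95% of random lists.

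The third comparison set the fold changes of the data sets side by side across 7106 genes measured in both. Spearman's rho was -0.07 and Pearson's r was -0.11, each with an exact two-sided p of 0.1 over the 10 splits of the tumours, the smallest these splits can give. Genes are not independent replicates, and the largest rho of another split had a size of 0.03. Of 525 genes at least 2-fold different in the adenovirus pair, 196, or 37.3%, had the same direction in mTERC- against mTERC+ tumours. These were 92 of the 312 genes higher in the TRF2DBDM pool and 104 of the 213 lower ones. The share was not set against that of all genes or of the other splits, so by itself it shows no opposite response. Among named genes, Serpina6 and Cyp2c23 had log2 values of -3.40 and -2.25 in the tumours and of 3.37 and 3.24 in the adenovirus pair. The macrophage, antigen presentation and gluconeogenesis lists had negative medians in the tumours and positive ones in the pair, while the neutrophil and mitosis lists had the opposite signs. The interferon list had negative medians in both, -0.26 and -0.71, but in the tumours it was 0.05 without mTERC+ tumour 2. The chromatin list had positive ones, 0.45 and 0.14, but in the pair it did not stand apart from random lists (percentile 82.2). The difference between the data sets in these lists was not tested.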

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

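All tests of technical explanations in this part were chosen after the results were seen, although the values without a tumour, with the Y-linked covariate and under other scalings had been planned.

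The Gapdh control of mTERC- tumour 2 had a 3'/5' ratio of 13.8, where the highest of the mTERC+ tumours was 1.18, in control probe sets that no comparison uses. Xist, the transcript of the inactive X chromosome, had a signal of 862 in mTERC- tumour 1, and of 104 and 38.4 in mTERC- tumours 2 and 3, where the highest mTERC+ tumour had 5.4. Eif2s3y, on the Y chromosome, had 70.5, 142 and 52.8 in mTERC- tumours 1, 2 and 3, and 199, 139 and 220 in the mTERC+ tumours. In mTERC- against mTERC+ tumours the list of male-biased liver genes had a median log2 difference of -0.26 (adjusted p = 0.0503 in camera). The female-biased list had a median of -0.01 (adjusted p = 0.832 in camera). A control probe set for the B2 repeat had a signal of 866 in the TRF2DBDM pool and 213 in the GFP pool. Another B2 control had 10759 against 7956, and a B1 control 7191 against 4996.

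Neutrophil marker genes were higher in mTERC- tumours, with a list median of 1.58 on the log2 scale. The RNA of mTERC- tumour 2, which is likely degraded, is argued against as the whole cause. Without that tumour the median was 1.97 and the difference of the list score, the mean of its members in each tumour, was 2.03 (SE 0.82). A trend with the level of Y-linked genes is argued against as well, since with that covariate these values were 1.76 and 1.95 (SE 0.82). All 4 globin probe sets had a lower mean in mTERC- tumours, with a median log2 difference of -1.10, which argues against more red cells left there. Globin cannot show how many neutrophils the remaining blood held, so neutrophils of the blood stay open. A labelling batch that holds the arrays with a low 18S control cannot be told apart from the group here: the median was 3.73 with a block for it, but that value rests on mTERC- tumour 1, the only mTERC- tumour outside the batch. The telomerase RNA status and an infection or inflammation of single animals stay open and untested, and so does a difference that goes with Xist, which was higher in every mTERC- than in any mTERC+ tumour, so more neutrophils in mTERC- tumours remain a hypothesis.

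Macrophage marker and antigen presentation genes were lower in mTERC- tumours, with list medians of -0.62 and -0.80. For antigen presentation, a trend with the level of Y-linked genes cannot be told apart, since that level partly follows the groups. With that covariate the median was -0.86 and the difference of the list score -0.96 (SE 0.33). Degraded RNA in mTERC- tumour 2 cannot be told apart there either. Without that tumour the median was -0.55, but the difference of the list score, -0.46 (SE 0.32), was not far above its SE. For the macrophage list neither cause can be told apart. The medians without that tumour and with that covariate were -0.61 and -0.66, but the differences of the list score, -0.66 (SE 0.89) and -0.60 (SE 0.88), were smaller than their SE. A single tumour may account for the macrophage pattern, because the median was -0.0172 without mTERC+ tumour 2. The antigen presentation median was -0.49 without that tumour, but the difference of the list score was -0.48 (SE 0.35), so this cannot decide. The antigen presentation scores were most extreme in mTERC+ tumour 2 (0.82) and mTERC- tumour 2 (-0.86), which were left out only 1 at a time. The 18S batch cannot be told apart from the groups for both lists, with medians of -0.31 and -0.26 with the block, where 1 mTERC- tumour is left outside the batch, and the telomerase RNA status and a difference that goes with Xist stay open and untested.

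Liver metabolic genes were higher in the TRF2DBDM than in the GFP pool. The scaling of the arrays is argued against, since the lowest median of the 4 lists under both other scalings was 0.65. A lower share of hepatocytes in the GFP sample would raise the markers of every other cell type there, but these moved apart: the macrophage list was higher in the TRF2DBDM pool (median 0.88), while the cholangiocyte and progenitor list (-0.63) and the neutrophil list (-0.66) were higher in the GFP pool, so more of those cells there stays open. RNA quality differed little, with 3'/5' ratios within 1.11-fold of each other. An effect of TRF2DBDM, a different virus dose reaching the liver and differences between the pooled mice stay open, since 1 pool per group cannot separate them.

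For the tumours, 10 splits of 3 against 3 cannot give a share under 0.05. The real split gave 1 gene past the threshold and the highest other split 1, and 3 splits gave as many. It gave 604 genes with an unadjusted p under 0.05 in limma, where the highest other gave 729, and 3 splits gave as many. It gave 11 lists in camera, where the other splits gave 3 to 9, and 1 split, the real one, gave as many. Groupings that mix the genotypes thus also passed lists in camera with the preset correlation. A list past that threshold therefore does not by itself show a difference between the groups. The split with 729 genes sets mTERC- tumours 2 and 3 with mTERC+ tumour 3, so it also keeps the arrays with a low 18S control together.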

How the results depend on the processing

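The 18S block, the neutrophil list without S100a8 and S100a9, the macrophage list without shared genes and the probe sets without a single symbol were chosen after the results were seen. No paired analysis was possible because the replicate numbers only follow the order of the samples and pair no tumours. Signals of many probe sets lie near the background of the arrays, where the pseudocount sets the fold change.

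In limma, 1 gene was higher in mTERC- tumours, and 0 were under median centring, a pseudocount of 1, the filter at percentile 75, no variance trend, the Y-linked covariate and the 18S block. Leaving out 1 tumour gave 0 to 4 genes higher and 0 to 2 lower. Genes with an unadjusted p under 0.05 numbered 604, against 918 with no level filter and 947 over all probe sets, where more were tested, and 326 with the filter at percentile 75, where fewer were. They numbered 1027 with the Y-linked covariate, 399 with the 18S block and 501 to 827 without 1 tumour. The 11 lists in camera became 0 with an estimated correlation, 0 in fry, 2 with the 18S block and 6 to 14 without 1 tumour. Which feature of the data causes these shifts was not tested where no other reason is given.

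The interferon list reversed to 0.0508 without mTERC+ tumour 2 (lowest without another tumour -0.508), and the hepatocyte function list to 0.00817 with the 18S block. The cause of these was not tested. Uhrf1 reversed to -0.57 and Nkd1 to -0.36 without mTERC- tumour 2 (highest without another tumour 1.64 and 2.01), because another probe set then had the highest mean and stood for the gene. The probe set also changed without mTERC- tumour 1, where they were 0.199 and 0.184. With the first probe set they were 1.04 and 1.47 without mTERC- tumour 2, and 1.41 and 1.77 without mTERC- tumour 1. With another probe set over all tumours Uhrf1 was -0.37, Nkd1 -0.34 and Sc5d 0.0925. When no probe set was chosen again, the chromatin list passed without mTERC- tumour 2 (adjusted p = 0.0310 in camera), and the hepatocyte function list was lost without mTERC+ tumour 1 (adjusted p = 0.0532 in camera). The antigen presentation and gluconeogenesis lists passed in camera under 16 of 16 alternatives set before the results were seen, with the preset correlation, but not with the 18S block (adjusted p of 0.157 and 0.860). The neutrophil list passed under the 15 of these that could test it and with the block; the filter at percentile 75 left too few of its members.

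For the adenovirus pair, the genes at least 2-fold higher numbered 360, but 678 with a pseudocount of 1 and 165 with the higher one, and those lower numbered 226, 435 and 81. Pearson's r between the data sets was -0.106, against Spearman's rho of -0.07. Of the values of called tumour lists under an alternative, 145 kept their direction and side of the threshold and 63 were no longer past it. Named tumour genes were followed under quantile normalization, the higher pseudocount, another probe set and each tumour left out, and S100a8 also with the 18S block. There 664 values kept both, 4 were no longer past it, all of S100a8, and 4 of other genes newly passed. Only S100a8 was past the threshold in the main fit, so for every other gene a kept side means that it stayed not past it. The adjusted p of S100a8 in limma was also above the threshold under median centring (0.0826), a pseudocount of 1 (0.112), the filter at percentile 75 (0.223), the mean of probe sets (0.287), no variance trend (0.280) and the Y-linked covariate (0.0575). Of those of adenovirus lists 114 stayed within 1.5 times and 11 did not, and of adenovirus genes 164 and 35.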

Other observations

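The test of the probe sets without a single symbol was chosen after the data were seen.

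Of 3014 probe sets without a single symbol, 1 passed as higher and 1 as lower in limma. The higher one had a signal of 6045 ± 5011 against 983 ± 158 (SD, n = 3 each, log2 difference 2.28, SE 0.39, adjusted p = 0.00349 in limma). The lower one is annotated to several alpha-globin genes, with a signal of 269.5 ± 122 against 1386 ± 523 (SD, n = 3 each, log2 difference -2.25, SE 0.38, adjusted p = 0.00349 in limma). All 4 globin probe sets had a lower mean, with log2 differences from -2.25 to -0.66, but the other 3 did not pass, and the beta-globin signal was 8678 ± 1303 against 21149 ± 4343. Alas2, the first enzyme of haem synthesis in red cells, had 241 ± 161 against 794 ± 167 and was the 1 erythroid member past the threshold adjusted over the list alone, while the erythroid list did not pass. Fatty acid and Wnt target genes not past the threshold over all genes included Scd1, at 11574 ± 701 against 21734 ± 3789, and Cyp2e1, at 1356 ± 757 against 315 ± 214. Cyp2e1 and Nkd1 passed adjusted over the Wnt list alone, but Nkd1 had a log2 difference of -0.34 with another probe set.

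In the adenovirus pair, genes of the unfolded protein response were mixed, with a median log2 ratio of -0.20 that did not stand apart from random lists. Sdf2l1, an endoplasmic reticulum protein, had a signal of 158 in the TRF2DBDM pool against 483, and Manf had 1013 against 2366. Ly6d had 391 against 2394, and Igfbp2 had 943 against 165. Cdkn1c, a cell cycle inhibitor, had 319 against 82.7, and Mdm2, a p53 target and regulator, had 269 against 125.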
